A study of Mus musculus with 6 samples.

How the data were processed

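RNA sequencing was done on bEnd.3 cells, a mouse endothelial cell line, kept for 24 h with mitochondria isolated from MLO-Y4 cells, an osteocyte-like mouse line, or with the same volume of medium alone. The mitochondria were given in 100 ul of medium, per the labels' protocols. There were 3 libraries in each group, called mitochondria and control here, and groups and replicate numbers were taken from the sample labels. Libraries were made with a stranded mRNA kit, per the labels' protocols. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

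The series has 1 table with 55401 genes, their coordinates, annotation terms and both estimated counts and FPKM values for the 6 libraries. Cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR are named, without stated roles, per the submitters' processing notes, together with the genome build GRCm38. The annotation release and the strand setting of the counting were not given in the sources used here. The deposited FPKM values are fragments scaled to transcript length and library size, per the file headers, and the authors list genes with a count of 0 at an FPKM of 0.0001. The deposited estimated counts are whole numbers, but they are not reads counted one by one. In 976 single-transcript genes with over 500 counts in every library, the count was proportional to FPKM times transcript length within 1% for 99.4% of genes. Of counts from 1 to 20, 36.6% were multiples of 4, against 25% if they were spread evenly. A sequenced fragment therefore probably contributes about 4 counts, so that the depth in fragments is nearer to the totals of 65394770 to 73376834 counts divided by 4. For this reason the floor was set at 12 counts per library, which stands for 3 fragments. Where all libraries of a group had a count of 0, the fold is a bound against that floor, and where they had a few counts under it, the ratio of fragments is given with its counting interval. At these depths 12 counts are 0.164 to 0.183 CPM. Floors and counting intervals cover counting error only, because the reads carry no molecular identifiers.

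The test fixed before the data were examined was limma on log2(FPKM + 1), since the table was expected to hold FPKM alone. Because it also holds counts, the main test became the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on the deposited estimated counts, which were already whole. It used TMM scaling, with factors of 0.996 to 1.007, and no covariate. The filter stayed as fixed, a mean FPKM of at least 1 over the 6 libraries, which left 12774 genes. Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are those of the fitted model, with standard errors derived from the F statistic. CPM values are counts scaled to library size after TMM. The limma 3.58.1 fit on log2(FPKM + 1) with an intensity trend is given as an alternative, and its fold changes understate the change of low genes.

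Of 40 gene lists, fixed at the same time as that test, 38 had at least 3 tested members. They were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists, and the test was repeated with an estimated correlation and with fry. Members were also counted after adjustment over each list alone. Terms of the deposited table with 10 to 500 tested genes were tested among called genes with a 1-sided Fisher exact test. The share of FPKM from the 13 mRNAs encoded in mitochondrial DNA was compared with an exact 2-sided permutation test, which with 3 against 3 libraries cannot give a p below 0.1. Genes are named by a rule fixed in advance. It takes the 10 largest fold changes in each direction among called protein-coding genes whose groups do not overlap, leaving out Gm and Rik names. Where fewer than 10 pass in a direction, the 5 genes with the smallest p in that direction that do not pass are added. It also takes up to 4 members with the smallest p in each called list, the mitochondrially encoded mRNAs, and 14 genes chosen for their roles in vessels and mitochondria. Other genes named were chosen after their values were seen, and this is said where they appear.

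The replicate numbers are shared by the groups, so the deviations of log2 CPM from the group means were compared. The correlation between same-numbered libraries across genes was 0.155, 0.101 and 0.231, all over 0.1, and the second principal component set replicate 3 of both groups apart. Between libraries of the 2 groups with different numbers the correlation was -0.216 to 0.084. Any pairing thus comes from the data and not from the labels. The main test and its list tests did not use the numbers, while the block and the sign-flip tests treated them as pairs. The fit with the replicate number as a block was planned as an alternative, and its value is given where it changes a call.

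Both tests were tested on simulated data drawn from the real means and library sizes for the mitochondria against control comparison over 12774 genes. The edgeR test recovered 46% of 50 genes changed 1.5-fold, 68% at 2-fold, 88% at 4-fold and 98% at 8-fold, with 11 false calls. The list test recovered 10 of 10 lists of 30 genes moved together by less than 1.5-fold and called 1 of 10 unmoved lists. Genes were drawn independently of each other in the simulation. In the data the estimated correlation within called lists ran from -0.061 for tip cell to 0.904 for interferon genes. The simulation therefore cannot show how often unmoved lists of correlated genes are called.

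Other settings tried were other pseudocounts, no filter and a stricter filter, TPM, median-of-ratios and quantile scaling, limma without the trend and with array weights, the replicate block, leaving out each library, other denominators and another term background. Added after seeing the data were DESeq2 1.42.0, counts divided by 4 and rounded, total-count scaling, leaving out pancreas and liver marker genes, the mitochondrial share of counts, camera over all annotation terms, 10 lists of tissue marker genes, and exact sign-flip tests of list means within same-numbered pairs. Alternatives defined on FPKM values were run with limma and the others with edgeR. The table's gene identifiers were compared with GENCODE vM21, which holds 99.5% of them. Genes in families of near-identical copies, such as the trypsins, and genes that overlap another gene are uncertain to the extent that the authors' counting could split their reads.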

Results

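The effect of osteocyte mitochondria on endothelial cells was examined by RNA sequencing of bEnd.3 cells, 3 libraries after 24 h with mitochondria isolated from MLO-Y4 osteocyte-like cells and 3 with medium alone. Library totals ranged from 65394770 to 73376834 estimated counts, and 22452 to 22875 genes had a count above 0. Pearson correlations of log2(FPKM + 1) across the tested genes were 0.975 to 0.981 among control libraries, 0.977 to 0.983 among mitochondria libraries and 0.968 to 0.981 between groups. The first principal component, with 34.2% of the variance, separated the groups, and the second, with 22.7%, set replicate 3 of both groups apart from the others.

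**Figure D1:**
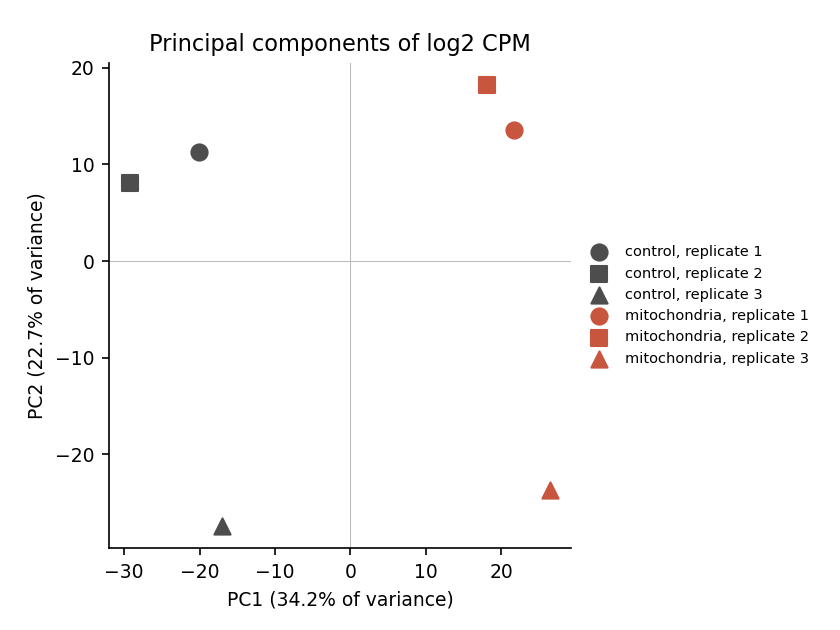
First and second principal components of log2 CPM over the tested genes, in arbitrary units, with 1 point per library (colour for group, shape for replicate number). Control libraries lie between -29.2 and -17 on the first axis and mitochondria libraries between 18.1 and 26.5, while replicate 3 of each group lies at -27.4 and -23.7 on the second.

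Few genes passed the threshold between cells with and without added mitochondria. Among the higher genes were Tspan14, a tetraspanin that regulates the protease ADAM10, Acvrl1, the endothelial BMP9 receptor ALK1, and Sun2, a nuclear envelope protein of the LINC complex. Most of the lower genes encode enzymes or other secreted products of the exocrine pancreas. In all, 21 of 12774 genes were called by edgeR's quasi-likelihood test at an adjusted p under 0.05, 8 higher and 13 lower with mitochondria, and 14 of them changed at least 2-fold, 2 higher and 12 lower. The limma fit chosen before the counts were known to be in the table called 17 genes, all among the 21, and DESeq2 called 360, 207 higher and 153 lower, among them all 21. With the replicate number as a block edgeR called 0 genes, with 2153 at an unadjusted p under 0.05, and 1 call was left without control replicate 1 and 12 without control replicate 3. Of 38 gene lists tested 9 were called by camera, 5 higher and 4 lower, with 0 under an estimated correlation and 5 without mitochondria replicate 1.

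Tspan14 (ENSMUSG00000037824, chromosome 14, 40906445 to 40966807 in GRCm38) rose 3.29-fold, from 12.4 ± 0.554 to 40.6 ± 1.73 CPM (SD, n = 3), with an edgeR adjusted p of 0.00202. Acvrl1 (ENSMUSG00000000530, chromosome 15, 101128522 to 101145336) rose 1.94-fold, from 32.8 ± 1.94 to 63.6 ± 2.57 CPM (SD, n = 3; edgeR adjusted p = 0.0111). Sun2, also on chromosome 15 (ENSMUSG00000042524, 79724070 to 79742534), rose 1.83-fold, from 57.2 ± 3.78 to 104.7 ± 3.26 CPM (SD, n = 3; edgeR adjusted p = 0.0117). The RNA helicase gene Ddx24 rose 1.41-fold, from 96.8 ± 4.51 to 136.8 ± 5.82 CPM, and the galactokinase gene Galk1 1.33-fold, from 87.9 ± 3.46 to 116.5 ± 1.43 CPM, with edgeR adjusted p-values of 0.0481 and 0.0483. Tspan14 lost its call only under the block (adjusted p = 0.0757), and Acvrl1 and Sun2 under the block (0.102 for both) and without control replicate 1 (0.117 for both). Ddx24 lost its call under 18 and Galk1 under 14 of 21 other settings, among them the block (0.187 and 0.186). Acvrl1, Sun2 and Ddx24 each overlap a predicted gene.

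**Figure D2:**
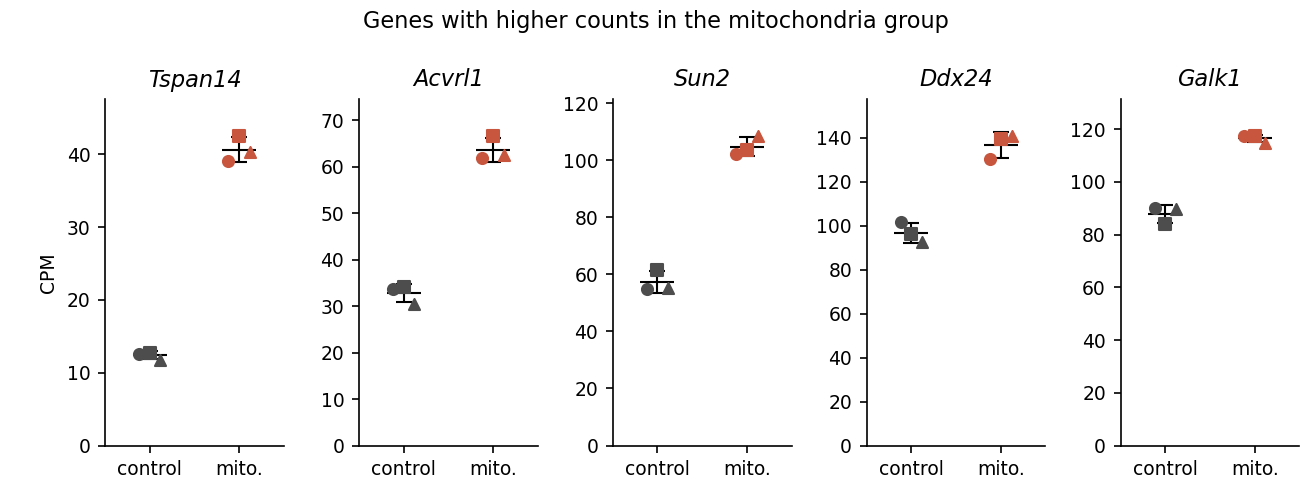
CPM of the 5 named genes that rose, with 1 point per library (shape for replicate number), the mean as a horizontal line and the SD as a bar, n = 3 per group, on axes that start at 0. The fold changes run from 3.29 for Tspan14 to 1.33 for Galk1.

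The other 3 higher genes fall outside the naming rule and were chosen after their values were seen. Gm26532, a long non-coding RNA gene on chromosome 8 (84208920 to 84209609) that overlaps the end of Mir24-2, had 6, 10 and 6 counts in the control libraries and 265, 291 and 261 in the mitochondria libraries. Taking 4 counts as a fragment, the ratio was 34.7 with an exact 95% counting interval of 15.7 to 95.6. The edgeR adjusted p was 0.00358, and 0.0757 under the block, where the call was lost. The processed pseudogene Gm12751 rose 1.64-fold and the protein-coding gene 5730409E04Rik 1.49-fold, both with an edgeR adjusted p of 0.0221. Under the block both lost their calls, at adjusted p of 0.137 and 0.165. Among the higher genes that did not pass, the 5 with the smallest p were Selenbp1 (1.36-fold, edgeR adjusted p = 0.0546), the glycolytic gene Pfkl (1.31-fold, 0.0612), the phosphoglucomutase gene Pgm1 (1.31-fold, 0.0661), Rhno1 (1.56-fold, 0.0772) and the mitochondrial gene Mgarp (2.48-fold, 0.0814).

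Of the 13 lower genes, 11 encode enzymes or other secreted products of pancreatic acinar cells, and 8 of these, Ctrb1, Cela2a, Clps, Cpa1, Prss2, Try4, Pnliprp1 and Sycn, had a count of 0 in all 3 mitochondria libraries. Against the floor of 12 counts per library they were at least 19.3-fold (Sycn) to at least 178-fold (Ctrb1) lower. The chymotrypsinogen gene Ctrb1, the most abundant, had 1974, 3156 and 1493 counts in the control libraries (edgeR adjusted p = 0.0221). The lipase gene Pnlip fell from 11.1 ± 2.99 to 0.12 ± 0.104 CPM and the chymotrypsin-like gene Ctrl from 6.35 ± 2.09 to 0.256 ± 0.157 CPM (SD, n = 3; edgeR adjusted p = 0.0483 and 0.0481). The KEGG term for pancreatic secretion held 9 of the 13 lower genes against 0.0489 by chance (1-sided Fisher exact test, adjusted p = 9.34e-17). In all 13 of 1959 terms were called for lower genes and 0 for higher genes, and 0 terms were called with a background of a mean FPKM of at least 5, which holds only 3 of the 13 lower genes. The Fisher test takes genes as independent of each other. Camera, run over the terms after the data were seen, gave pancreatic secretion an adjusted p of 2.38e-12, and 0.898 with an estimated correlation. The summed level of 38 listed acinar genes was 170.0 ± 48 CPM in control and 3.88 ± 0.0326 CPM in mitochondria libraries (SD, n = 3). The acinar gene 2210010C04Rik, named after its values were seen, fell from 8.23 ± 2.03 to 0.128 ± 0.0499 CPM (SD, n = 3; edgeR adjusted p = 0.00704). Under the block and without control replicate 1 each of the 11 acinar genes lost its call. The adjusted p was 0.102 for 2210010C04Rik under the block, and up to 0.188 for the 10 others. Ctrb1 lost its call under 2 of 20 other settings, Pnlip and Pnliprp1 under 7 of 19 and Ctrl under 8 of 19. Cela2a, Cpa1, Pnliprp1, Sycn and Try4 also lost theirs with counts divided by 4. Without control replicate 2 the same genes and Prss2, Ctrl and Pnlip lost theirs. None of the 10 changed direction in any setting that tested it. Ctrb1 overlaps Mir7076, Clps Mir6969, Cela2a Casp9 and Ctrc, and Sycn Samd4b. The trypsin genes Prss2 and Try4 belong to a family of near-identical copies whose reads the counting could split.

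Transcripts of a further tissue, examined after the acinar values were seen, also varied between libraries. The liver transcript Alb had 1092, 1835 and 1418 counts in the control libraries and 9, 1314 and 832 in the mitochondria libraries, and Apoa2 had 239, 394 and 314 against 0, 274 and 328. The summed level of the listed liver genes other than Trf was 66.0, 85.3 and 72.5 CPM in the control and 3.7, 61.6 and 53.5 CPM in the mitochondria libraries, lower in each of the latter (exact 2-sided permutation p = 0.1, the smallest possible). Without the pancreas and liver marker genes, 6 genes were called, all higher, and without mitochondria replicate 1, the library with 9 counts of Alb, 27 were called.

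**Figure D3:**
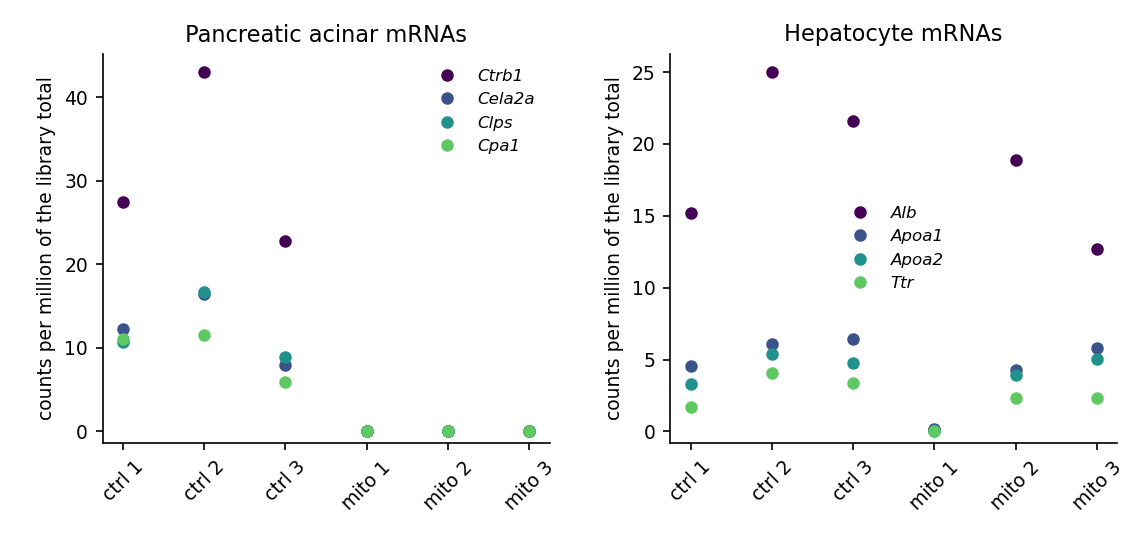
CPM of the library total for 4 pancreatic acinar mRNAs (left) and 4 hepatocyte mRNAs (right), with 1 point per gene and library on linear axes. The acinar mRNAs are at 0 in all 3 mitochondria libraries, while the hepatocyte mRNAs are lowest in mitochondria replicate 1, where Alb has 9 counts.

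The remaining 2 lower genes were chosen after their values were seen. Nphs1, which encodes the podocyte protein nephrin, fell from 29.7 ± 3.92 to 3.94 ± 1.84 CPM, and the ubiquitin ligase gene Cul4a fell to 0.754-fold, from 175.8 ± 1.52 to 132.5 ± 4.31 CPM (SD, n = 3; edgeR adjusted p = 0.0483 and 0.0307). Under the block both lost their calls, at edgeR adjusted p of 0.129 for Nphs1 and 0.137 for Cul4a. Nphs1 overlaps Nphs1os and Rps12-ps4, and Cul4a overlaps Mir7065. Without the pancreas and liver marker genes in the fit the fold changes stayed at 0.133 for Nphs1 and 0.754 for Cul4a and the unadjusted edgeR p at 7.8e-05 and 3.82e-05. Both calls were then lost, at adjusted p of 0.0994 and 0.0696, as fewer genes with small p-values entered the adjustment.

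As groups, genes of the response to low oxygen and of glycolysis were higher with mitochondria. Of 24 tested genes of the hypoxia list 22 were higher, with a median log2 fold change of 0.29, and of 21 glycolysis genes 19 were higher, with a median of 0.22. The camera test gave adjusted p-values of 1.76e-11 and 2.24e-10, against 0.495 and 0.498 with an estimated correlation. In each list 0 members were called over all genes tested and 10 were higher when adjusted over the list alone. The lists share 6 members, Hk2, Ldha, Pdk1, Pfkfb3, Pgk1 and Slc2a1.

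Among hypoxia genes, the collagen prolyl hydroxylases P4ha2 and P4ha1 were 1.37-fold and 1.16-fold higher, and the oxygen sensors Egln1 and Egln3 were 1.36-fold and 1.24-fold higher, with P4ha2 at 68.9 ± 5.43 in control and 94.1 ± 2.37 CPM in mitochondria libraries (SD, n = 3). Their edgeR adjusted p-values were 0.01 for P4ha2 and 0.0143 for the other 3 over the list alone, and 0.128 to 0.215 over all genes. Vegfa, the angiogenic growth factor, stood at 119.9 ± 13.9 and 153.9 ± 9.04 CPM (SD, n = 3), 1.28-fold, with an edgeR adjusted p of 0.0285 over the list alone and 0.256 over all genes. In glycolysis, Pfkl, Hk1, Pfkm and Aldoa had fold changes of 1.31, 1.26, 1.15 and 1.33, with edgeR adjusted p-values of 0.00282 to 0.0148 over the list alone and 0.0612 to 0.224 over all genes. DESeq2 called 10 of the hypoxia and 9 of the glycolysis genes over all genes, all higher.

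**Figure D4:**
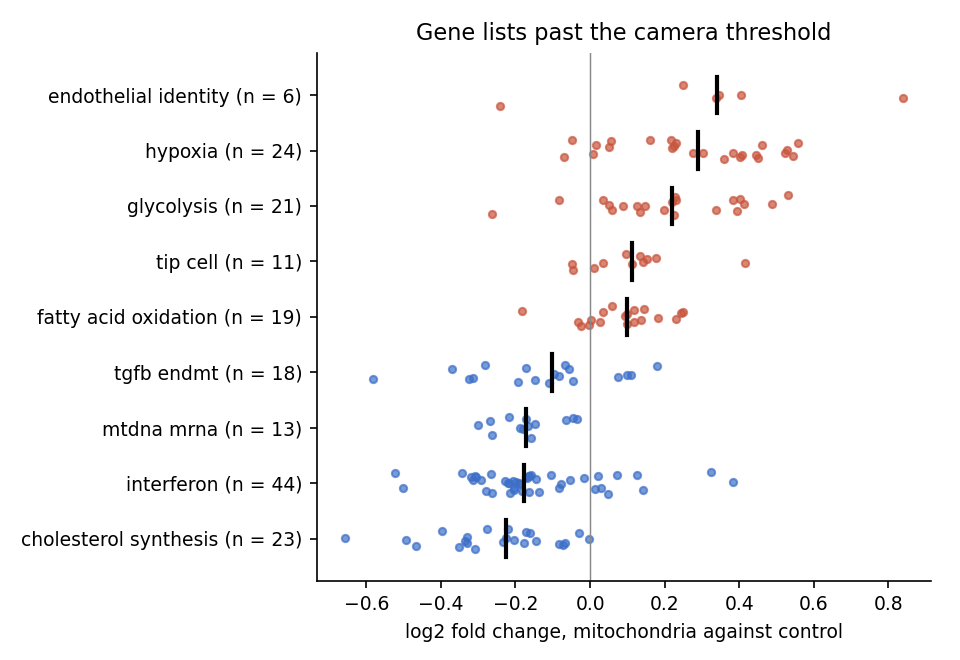
Log2 fold change, mitochondria against control, of each tested member of the 9 gene lists past the camera threshold, with 1 point per gene and a vertical bar at the list's median. Medians are 0.29 for hypoxia and 0.22 for glycolysis, and all 23 cholesterol genes (20 with TPM and 22 with total-count scaling) and all 13 mitochondrially encoded mRNAs (12 with TPM and 6 with quantile normalisation) lie below 0.

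The lists of cholesterol synthesis and fatty acid oxidation differed in direction. All 23 tested genes of cholesterol synthesis and uptake were lower, but 3 were higher with TPM, 3 with limma array weights and 1 with total-count scaling, as were 6 without control replicate 2, 1 without control replicate 3, 2 without mitochondria replicate 1 and 1 without mitochondria replicate 2. The median log2 fold change was -0.23 (camera adjusted p = 2.46e-06; adjusted p = 0.832 with an estimated correlation), and edgeR called 0 members over all genes or adjusted over the list alone, while DESeq2 called Fdft1 over all genes (adjusted p = 0.00111). The smallest p was that of the squalene synthase gene Fdft1, at 92.9 ± 17.9 and 58.9 ± 3.26 CPM (SD, n = 3, edgeR adjusted p = 0.215). The next smallest were those of Stard4, Idi1 and Ebp, with fold changes of 0.859, 0.724 and 0.826. The median was -0.075 without control replicate 2 and -0.12 with array weights. The mean log2 CPM of the list was 5.72, 6.16 and 5.79 in the control libraries and 5.62, 5.62 and 5.71 in the mitochondria libraries. Of 19 fatty acid oxidation genes 15 were higher (camera adjusted p = 0.0135; adjusted p = 0.515 with an estimated correlation), with 0 called by edgeR over all genes and 3 higher when adjusted over the list alone, Acadvl (1.17-fold), Eci2 (1.19-fold) and Slc25a20 (1.19-fold). DESeq2 called Acadvl and Eci2 over all genes, at adjusted p of 0.000938 and 0.00138. The mean log2 CPM of this list overlapped between the groups, at 5.78, 5.79 and 5.88 in the control and 5.94, 5.76 and 5.92 in the mitochondria libraries (exact 2-sided permutation p = 0.4), and was higher in 2 of 3 same-numbered pairs. Its call was lost without control replicate 2 (0.0571) or mitochondria replicate 1 (0.0647), and Hadh, at 1.13-fold, did not pass.

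The mRNAs encoded in mitochondrial DNA, which the donor organelles also carry, were lower as a list. All 13 had a log2 fold change below 0, from -0.30 for mt-Cytb to -0.035 for mt-Nd6, although 7 turned above 0 with quantile normalisation, 1 with TPM and 2 without mitochondria replicate 2, where the median was -0.094 in place of -0.17. By edgeR 0 were called over all genes or adjusted over the list alone, and by DESeq2 mt-Cytb was called lower over all genes (adjusted p = 0.0073), while the list passed (camera adjusted p = 2.91e-05; adjusted p = 0.832 with an estimated correlation). With quantile normalisation the list lost its call. These mRNAs made up 16.4% ± 0.653 of FPKM in control and 15.2% ± 1.24 in mitochondria libraries (SD, n = 3), a difference of -1.26 percentage points (exact 2-sided permutation p = 0.2, with 0.1 the smallest possible). Within same-numbered pairs the share was lower in 3 of 3 (exact sign-flip permutation p = 0.25, the smallest possible). The difference was -0.661 without mitochondria replicate 2 and -1.89 without mitochondria replicate 1. The nuclear genes of oxidative phosphorylation did not pass, with 30 of 74 higher (camera adjusted p = 0.55), nor did those of the mitochondrial ribosome (27 of 77 higher, 0.105), the citric acid cycle (7 of 22 higher, 0.877), mitochondrial biogenesis and dynamics (17 of 27 higher, 0.576), mitophagy (10 of 17 higher, 0.576) or the mitochondrial unfolded protein response (5 of 12 higher, 0.913). Tfam, the mitochondrial transcription factor, Ppargc1a and the mitochondrial transport gene Rhot1 had fold changes of 1.09, 0.914 and 0.948, with edgeR adjusted p-values of 0.463, 0.612 and 0.86.

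Endothelial gene lists gave calls that were lost under several settings. Of 11 tested tip cell genes 9 were higher (camera adjusted p = 0.0299; 0.0588 with the replicate block; adjusted p = 0.498 with an estimated correlation). With 0 called by edgeR over all genes, and Apln called by DESeq2 (adjusted p = 2.59e-05), Apln alone was higher when adjusted over the list alone, 1.33-fold from 29.1 ± 1.35 to 38.8 ± 1.42 CPM (SD, n = 3), while Cd34, Flt4 and Angpt2 had fold changes of 1.13, 1.1 and 1.11. The call was lost without control replicate 1 (0.0793) or 3 (0.132) or mitochondria replicate 1 (0.0647) or 2 (0.149), and also with no filter (0.067), a mean FPKM of at least 5 (0.0698) and fry (0.0979). Only 6 of 20 endothelial identity genes were expressed enough to test (camera adjusted p = 0.0153, 0.0565 with limma; adjusted p = 0.542 with an estimated correlation). Of the 6 tested genes 5 were higher, with a median log2 fold change of 0.34 for the list. Over the list alone Tie1 (1.26-fold), Ly6a (1.79-fold) and Flt1 (1.27-fold) were higher and Eng (0.846-fold) was lower. Ly6a had 20.2 ± 3.25 CPM in control and 36.2 ± 13.7 in mitochondria libraries (SD, n = 3), and its log2 fold change of 0.84 fell to 0.49 without mitochondria replicate 3. Over all genes edgeR called 0 and DESeq2 called Tie1 and Ly6a higher, at adjusted p of 0.032 and 0.0466, and the list lost its call without control replicate 2, at 0.0571. It also lost it with each of 3 pseudocounts in limma, with no filter (0.11), a mean FPKM of at least 5 (0.052), TPM (0.0553), limma without the trend (0.0558) or with array weights (0.0753), and fry (0.266). In 13 of the 20 the FPKM stayed below 1 in all 6 libraries, among them Pecam1 at 0.193 ± 0.0142 and 0.157 ± 0.016, Cdh5 at 0.0978 ± 0.0738 and 0.0365 ± 0.0341 (SD, n = 3), and Cldn5, listed at 0. The low levels of these 13 go against the endothelial label of the line. Other members of the list were well expressed, led by Eng at 70.0 ± 7.84 and 59.7 ± 2.14 FPKM and Flt1 at 26.0 ± 3.7 and 33.3 ± 2.94 FPKM (SD, n = 3). The markers thus do not settle the label. The endothelial, tip cell and angiogenesis lists are therefore read here as lists of genes and not as a sign of cell type.

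Of 18 genes of TGF-beta signalling and endothelial-to-mesenchymal transition 14 were lower (camera adjusted p = 0.0417, 0.0565 with limma; adjusted p = 0.498 with an estimated correlation). None passed over all genes by edgeR, with 0 called against 2 by DESeq2, and over the list alone Cdh2 (0.774-fold) and Snai2 (0.804-fold) were lower, while Fn1 (1.13-fold) and Tgfb2 (0.668-fold) did not pass. The call was lost without control replicate 1 (0.0501), 2 (0.193) or 3 (0.0517) or mitochondria replicate 1 (0.117) or 2 (0.0625), and also with each of 3 pseudocounts in limma, a mean FPKM of at least 5 (0.249), quantile normalisation (0.0552), limma without the trend (0.0558) or with array weights (0.0741), and fry (0.0979). Of 34 angiogenesis genes 19 were higher (camera adjusted p = 0.752; median log2 fold change 0.036, mean -0.003), and edgeR called Acvrl1 alone over all genes, while DESeq2 called 4, 3 higher and 1 lower. Adjusted over the list alone, Acvrl1 was higher and Slit2, a guidance cue named after its values were seen, was lower, at 395.7 ± 59.4 and 217.8 ± 12.3 CPM (SD, n = 3; 0.55-fold, edgeR adjusted p = 0.00284 over the list alone and 0.0668 over all genes). Barrier and junction genes (camera adjusted p = 0.877), Notch genes (0.486) and endothelial activation genes (0.877; median -0.039, mean 0.058) did not pass. Kdr, the main VEGF receptor, had a mean FPKM of 0.949 and lay below the filter, as did Dll4 (0.0316) and Esm1, which is listed at 0.

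Interferon genes were highest in replicate 2 of both groups. Of 44 tested 35 were lower with mitochondria (camera adjusted p = 0.0237; adjusted p = 0.926 with an estimated correlation), yet the mean log2 CPM was 6.98, 7.43 and 6.88 in control replicates 1 to 3 and 6.69, 7.4 and 6.7 in mitochondria replicates 1 to 3. With the replicate block 37 were lower (adjusted p = 1.04e-10), and within same-numbered pairs the mean was lower in 3 of 3 (exact sign-flip permutation p = 0.25, the smallest possible). By edgeR and DESeq2 0 members were called over all genes, and by edgeR 0 over the list alone, and log2 fold changes were 0.32 for Irf9, -0.52 for Ifi47, -0.17 for Ddx58 and 0.38 for Psmb9. In fits without the block, which break a pair when a library is left out, the direction reversed without control replicate 2, at an adjusted p of 0.851, and the call was lost without mitochondria replicate 1 (0.848) or 3 (0.73). Ifit1 and Cxcl10 had fold changes of 0.805 and 0.909, Vcam1 0.766, Icam1 1.11, the haem oxygenase gene Hmox1 1.11 and the proliferation marker Mki67 1.04, with edgeR adjusted p-values of 0.362 to 0.846. NF-kB genes (camera adjusted p = 0.55), G1/S genes (0.61) and G2/M genes (0.61) did not pass.

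Lists of markers of other cell types did not pass the test. Osteocyte genes, those of the donor cell type, had 5 of 10 tested members higher (camera adjusted p = 0.55), with Spp1 at 82.6 ± 6.16 and 93.9 ± 1.74 FPKM (SD, n = 3) and Dmp1 and Mepe listed at 0. Mural and fibroblast genes (0.877) were led by Col3a1 at 54.7 ± 20.8 and 47.6 ± 10.5 FPKM, and macrophage and leukocyte genes (0.877) by Cd68 at 6.36 ± 1.96 and 8.68 ± 0.943 FPKM (SD, n = 3). The epithelial list had 1 tested member, Krt18, and the erythroid list 0, so neither was tested. Genes that report on RNA quality did not pass (0.877). The lists of lysosome, antioxidant, integrated stress response, endoplasmic reticulum stress, heat shock, p53, senescence, lipid synthesis, collagen and matrix, immediate early, cytosolic ribosome and nucleotide sensing genes did not pass either, with camera adjusted p-values of 0.105 to 0.877.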

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

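The alternatives with DESeq2, counts divided by 4, total-count scaling, the marker genes left out and the counts of mitochondrial mRNAs were chosen after seeing the data. The main counts were 21 called genes, 14 of them changed at least 2-fold, and 9 gene lists. Of 97 other values of the main results, 72 stayed on their side of the threshold or within 1.5 times the main value. Those of the mitochondrial share could not cross the threshold, because their exact tests cannot give a p under 0.05. Only a change of direction could have counted against them. With a mean FPKM of at least 5, which removes most acinar genes from testing, 8 genes were called, 3 of them changed 2-fold, all 8 among the 21. With the replicate block 0 genes were called by edgeR, 0 at 2-fold, and 0 of the 21 stayed, with 2153 genes at an unadjusted p under 0.05, against 17 by limma and 360 by DESeq2 without a block; 8 lists stayed called, and among lists the block ended the tip cell call alone. The blocked difference in mitochondrial FPKM share was -1.26 percentage points. DESeq2 gave 360 calls, 33 of them 2-fold, and left 508 genes without an adjusted p. Counts divided by 4 gave 9 genes at 2-fold, and without pancreas and liver marker genes there were 6 calls, 2 of them 2-fold, all 6 among the 21, since removing genes with small p-values raises the adjusted p of the rest; the cause of the other differences was not tested. Leaving out 1 library gave 1 (control replicate 1) to 27 (mitochondria replicate 1) calls, 1 to 18 at 2-fold, 1 to 15 of the 21 kept, 5 to 9 lists and a difference of -1.89 to -0.661 percentage points in the mitochondrial share of FPKM. With an estimated correlation 0 lists were called and with fry 0. The term background of a mean FPKM of at least 5, which holds 3 of the 13 lower genes and 1466 terms, gave 0 called terms against 13. Among the named genes, those whose sign changed were genes that edgeR did not call. With quantile normalisation the median log2 fold change of the mitochondrial mRNA list was 0.012, against -0.17, and log2 fold changes were 0.016 for mt-Nd2, 0.012 for mt-Nd5, 0.041 for mt-Nd4l, 0.034 for mt-Atp8, 0.027 for mt-Co3, 0.102 for mt-Co2 and 0.078 for mt-Nd6. With TPM mt-Nd6 had 0.006. Leaving out 1 library gave -0.183 to 0.023 for mt-Co2 and -0.108 to 0.032 for mt-Nd6, both highest without mitochondria replicate 2, -0.009 to 0.106 for Mki67, lowest without control replicate 2, and -0.443 to 0.029 for Cxcl10, highest without control replicate 2. For the interferon list it gave adjusted p-values of 4.51e-17 to 0.851, with the direction reversed without control replicate 2, where the median log2 fold change was 0.001. Depth limits genes near the floor of 12 counts, such as Gm26532 in the control libraries.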

Other observations

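The tests over annotation terms, the tissue marker lists and the tests of explanations below were chosen after the results were seen, except the test of the hypoxia genes outside the glycolysis list at the preset correlation. Camera over 290 KEGG pathways called 11, 7 higher and 4 lower with mitochondria, and 0 with an estimated correlation. Among the higher ones were glycolysis (45 genes, adjusted p = 0.0028; 0.996 with an estimated correlation), the pentose phosphate pathway (22 genes, 0.00468; 0.996), HIF-1 signalling (77 genes, 0.0063; 0.898), and fructose and mannose metabolism (29 genes, 0.0163; 0.898). Steroid biosynthesis was lower (14 genes, adjusted p = 0.00468; 0.996 with an estimated correlation). Of 1669 GO terms 8 were called, 0 with an estimated correlation, with protein secretion (24 genes, adjusted p = 0.0174; 0.998) and brown fat cell differentiation (11 genes, 0.0208; 0.998) among the higher ones and the response to interferon-beta (25 genes, 0.0231; 0.998) among the lower ones.

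All 26 liver marker genes reached 12 counts in every control library, and 4 of the 26 did so in every mitochondria library. Each of the others fell short in mitochondria replicate 1 alone. The summed level of the list was 203, 230 and 204 CPM in the control and 138, 190 and 184 CPM in the mitochondria libraries. Most of it came from Trf, which had 9390 counts in mitochondria replicate 1, where Alb had 9. Of 8 intestinal, 7 lung, 7 testis and 9 islet markers, 0 reached 12 counts in all libraries of either group. The summed levels of the kidney list were 26.6, 31.6 and 34.1 CPM against 3.74, 3.78 and 7.44 CPM, nearly all from Nphs1, and without it 1.31, 0.758 and 1.23 against 0.629, 1.11 and 1.39 CPM (exact permutation p = 0.8). The sums of the brain list were 9.55, 8.99 and 8.89 against 15.3, 12.6 and 13.3 CPM. Most came from Slc17a7, with 374, 312 and 328 against 693, 564 and 530 counts. The counts of each other detected brain marker overlapped between the groups. The sums of the muscle list were 13.5, 16.5 and 14.2 against 13.8, 13.9 and 16.2 CPM and those of the lymphoid list 7.96, 6.65 and 8.44 against 8.72, 8.14 and 8.91 CPM.

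Of 38 listed acinar genes, 28 reached 12 counts in every control library, and 22 did so while staying under it in every mitochondria library. Reads moving between similar enzyme genes are argued against, since the summed level of 38 listed acinar genes in the mitochondria libraries was 2.29% of that in the control libraries, 3.88 ± 0.0326 against 170.0 ± 48 CPM (SD, n = 3), and 2 of the 38 reached 12 counts in every mitochondria library. RNA of another tissue in the control libraries is a candidate explanation. Of 27 listed acinar genes that were not called, 14 reached 12 counts in every control library and stayed under it in every mitochondria library. A loss of transcripts that the cells themselves make would follow the groups, as the called acinar transcripts do. RNA of another tissue can follow the groups but need not, so these explanations cannot be told apart here. The liver transcript Alb, for example, had 9 counts in mitochondria replicate 1 but 1314 and 832 in replicates 2 and 3. Among the listed acinar genes Pnliprp2 did not follow the groups, with 151, 176 and 86 counts in control and 134, 135 and 155 in mitochondria libraries. The highest control count of the acinar transcription factor gene Ptf1a, 0, may only reflect depth.

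The list of mitochondrially encoded mRNAs was lower with mitochondria by camera at the preset correlation alone (adjusted p = 2.91e-05; 0.832 with an estimated correlation), edgeR called 0 of the 13, their FPKM share overlapped between the groups (exact permutation p = 0.2), and with quantile normalisation 7 were higher. Nuclear copies of mitochondrial DNA were summed only from a short stretch of the nuclear genome. A shift of reads to these copies is argued against, because both together were also lower, by -0.897 percentage points of counts (exact permutation p = 0.1, the smallest possible). The copies alone went from 1.57% ± 0.055 to 1.22% ± 0.092 (SD, n = 3). A shift to nuclear copies elsewhere was not tested. A lower yield of mitochondrial RNA in library preparation may still account for a difference. The rRNA genes do not decide this, with log2 fold changes of -0.24 for mt-Rnr1 and -0.025 for mt-Rnr2. A response of the recipient cells stays open as well, and was not tested apart from the groups.

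The hypoxia list was called at the preset correlation and not with an estimated one (adjusted p = 0.495) or with fry (0.0705), and its higher level may be a response to the added organelles, which is a hypothesis. The rise was not shared by the tested genes as a whole. With total-count scaling their median log2 fold change was 0.009, against 0.30 for the hypoxia list. Scaling to library totals keeps the median gene near 0, so it cannot show a change of all genes together. Nor did the 6 shared genes alone carry it. The 18 hypoxia genes outside the glycolysis list gave an unadjusted camera p of 4.59e-10, and 0.0102 with an estimated correlation, with 16 higher. With an estimated correlation the unadjusted camera p was 0.013 for the whole hypoxia list and 0.03 for the 6 shared genes. Cell density, oxygen or handling that differed between the groups cannot be told apart from the treatment, because they would follow the groups. The list's mean log2 CPM was higher by 0.29 in the mitochondria libraries, with every mitochondria library above every control library (exact permutation p = 0.1, the smallest possible).

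The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 21 called genes against at most 10 in the other splits, and 14 changed at least 2-fold against at most 6, so that 1 split, the real one, gave as many. For gene lists the real split gave 9 and the highest other 16, and 5 of the 10 splits called at least as many. With replicate numbers taken as pairs, the 3 other splits that part all 3 pairs called 2 to 5 lists and 0 to 10 genes. The 6 that part 1 pair called 3 to 16 lists.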
